A study of Mus musculus with 8 samples.

How the data were processed

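TSA, a mouse mammary adenocarcinoma line syngeneic to Balb/c mice, was injected under the skin either as wild-type (WT) cells or as cells in which Ripk1 had been knocked out (KO), and tumours were taken after 14 days, per the labels' protocols. Ripk1 encodes a kinase that acts below death receptors and Toll-like receptors. Per the series design text, 2 tumours of each genotype were dissociated, stained for CD45, the surface protein of leukocytes, and sorted into live CD45+ and CD45- cells, which gave 8 libraries in 4 groups of 2. The p-values for single genes and for shares below measure the spread between these libraries, and so between 2 tumours per genotype. Cells were not treated as replicates.

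The deposited matrices hold raw UMI counts, whole numbers of distinct transcripts per gene and barcode. They were made from 10x 3' version 2 libraries with Cell Ranger 2.1.0 on the mouse build mm10, per the submitters' processing notes. The annotation release used for counting is not given in the sources used here. Per the file headers, the authors' 2 cell tables, 1 for each sort, give for each kept cell its library, its UMI count, its number of genes, the percent of its UMIs from mitochondrial genes and a cluster number. The CD45+ table also holds the authors' cell type names. Column names of these tables point to an integrated Seurat clustering, and no expression value from it was used here.

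The 8 matrices hold 30652 barcodes, 28692 genes and 146372445 UMIs. The UMI total of a kept cell in the authors' tables equalled the matrix total for 56.2% to 83.3% of the cells of a library and differed by at most 202 UMIs elsewhere. All kept cells had more than 500 and fewer than 4000 genes and under 10% mitochondrial UMIs. These limits were read from the kept cells. They leave 28049 barcodes, of which the authors kept 17449, and no reason for leaving out the other 10600 is given in the sources used here. The authors' CD45- table holds 0 cells of KO CD45- replicate 1, a library with 149 barcodes, of which 69 lie within the limits.

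Cell types in the CD45+ libraries are the authors' own. Their labels Mac_0 to Mac_4, Mono/Mac and Mono_1 were summed as monocytes and macrophages, their CD4 and CD8 labels as T cells, and DC1 to DC3 as dendritic cells, while NK, Neutrophil/MDSC, mpDC and B Cell were used as given. The CD45- table names no cell types. Barcodes within the limits were therefore clustered here with scanpy 1.11.5 on log-transformed counts scaled to 10000 per cell, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2 installed, igraph implementation used). Clusters with at least 100 CPM of both Krt8 and Krt18, under 5 of Ptprc, under 100 of Xist and at least 20% of their CD45- cells kept by the authors were called keratin-expressing. This rule was set after the data had been seen. The tested CD45- class consists of the cells the authors kept in the other 3 libraries and of the 22 keratin-expressing cells of KO CD45- replicate 1. It departs from the design fixed before the data were examined, which foresaw a class named cancer cells. That name was not used, because 1 cluster inside the class is led by the muscle genes Acta1, Des and Mylpf. A cluster that the rule kept out held 5.00% ± 0.916 of WT and 6.92% ± 8.66 of KO CD45- barcodes (SD, n = 2), and an Xist-expressing epithelial cluster held 0.682% ± 0.935 and 1.47% ± 2.02 (SD, n = 2). Whole CD45- sums cover all barcodes within the limits, since 1 library has no kept cells. Whole CD45+ sums cover the kept cells.

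Raw UMI counts were summed per class and library for libraries with at least 10 cells of the class, and KO was tested against WT with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and filterByExpr. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a class, and genes were called at 0.05. Log2 fold changes are KO minus WT, with 1 standard error. Numbers of cells per class were tested with edgeR on cell counts, with the number of cells as offset. With 2 against 2 libraries an exact permutation test cannot go below p = 0.333, so none was run. Differences in the KO effect between 2 classes were tested as interactions, with the library as a block where both classes came from the same libraries. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a class. These p-values compare the genes of a list with the other genes, at a fixed allowance for how genes vary together between libraries. They do not measure how far a list as a whole varies between tumours. Lists with fewer than 3 measured members were left out. No camera call in any class held with a correlation estimated from the data, and fry, which tests whether a list's genes move on balance 1 way, called 0 lists in each class.

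The 20 lists, the tests, the rule for genes named in the text and most alternatives were fixed before the data were examined. The lists covered death receptor and RIPK signalling, NF-kB targets, chemokines and myeloid growth factors, interferon-stimulated genes, IFN-gamma response with MHC class I, MHC class II, suppressive myeloid genes and inflammatory macrophage genes. The others were cytotoxic effectors, T cell activation and checkpoint, naive and memory T cell, regulatory T cell, cell cycle, hypoxia and glycolysis, epithelial genes, mesenchymal and extracellular matrix genes, p53 targets, the unfolded protein response, dissociation-induced immediate early genes and haemoglobin. Named in each class were Ripk1 and the 6 called genes with the largest positive and the 6 with the largest negative fold change. These had a mean of at least 20 CPM and both KO libraries on the same side of both WT libraries. The 3 members of each list with the smallest unadjusted p were named in keratin-expressing cells and in monocytes and macrophages. In T cells and NK cells this was done for the cytotoxic effector and the T cell activation and checkpoint lists only. Predicted genes, mitochondrial and ribosomal genes and receptor segments were left out of the largest changes. The rule named 123 genes. Names outside it are marked in the text as chosen after their values were seen.

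Alternatives fixed beforehand were DESeq2 1.42.0, RLE scaling, no low-count filter, the replicate number as a block, each library left out in turn, cells with at least 1000 UMIs, removal of barcodes marked by Scrublet, limma on arcsine shares, TMM factors for shares, and an estimated correlation or fry for lists. A further 7 were chosen after seeing the data. They were 4 other choices of keratin-expressing cells, removal of the top 6% of doublet scores in each library, and all CD45+ barcodes within the limits for whole sums and for shares. Scrublet, run per library at an expected rate of 6%, marked 23 of 28049 barcodes (0.0820%), and so did not work as a doublet filter on these data. Doublets were otherwise left in. A further test of the share of gamma-delta type cells among T cells, which decided neither way by its bounds, and some single gene results are not reported here.

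The depth per library ran from 1294150 UMIs (KO CD45- replicate 1) to 27499928 UMIs (KO CD45- replicate 2), and intervals on UMIs are exact Poisson 95% intervals that cover counting error only. A count of 0 was read as allowing up to 3 counts. The tests were also run on simulated counts drawn from the real means, depths and spreads, with 200 genes changed, in 6 draws. With a spread that differed from gene to gene, 4-fold changes were recovered for 89.2% of genes in the keratin-expressing class, 86.3% in monocytes and macrophages, 62.5% in neutrophils, 83.2% in T cells, 79.7% in NK cells, 84.3% in whole CD45+ and 14% in whole CD45- libraries. The corresponding percentages for 2-fold changes were 40.3%, 26%, 6%, 18.7%, 19.8%, 29.7% and 0.167%. Where all libraries of a class were set to their geometric mean depth, with the same spreads, the percentages were 12.3%, 13.2%, 5.33%, 8%, 15.7%, 27.2% and 0% for 2-fold and 72.7%, 82.8%, 56.8%, 66.5%, 77.2%, 84.5% and 0% for 4-fold changes. At the real depths false calls made up 31.9%, 13.9%, 5.30%, 9.75%, 6.28%, 12.4% and 53.0% of the calls in the same order, and 4.90%, 3.51%, 2.80%, 4.14%, 5.11%, 5.18% and 9.24% where the spread followed a trend on the mean. With no gene changed the keratin-expressing class gave 28 to 57 calls, against at most 10 in any other class. In simulated shares a cluster raised 4-fold was called in 43 of 50 simulations, and 20 of 850 other cluster tests were called. The spread between libraries in these simulations was a chosen value, not one estimated from the data. In the data the NK cluster, at 4.08-fold, was not called (edgeR adjusted p = 0.214). The simulated shares therefore do not measure the power of the share tests on these libraries.

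Gene coordinates are from GENCODE M21 on GRCm38/mm10. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.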

Results

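Single-cell RNA libraries were compared between TSA tumours grown from WT and from RIPK1 KO cancer cells, separately for sorted CD45+ leukocytes and CD45- cells, with 2 libraries per genotype and sort. The CD45+ libraries held 8927 and 3301 barcodes (WT replicates 1 and 2) and 2109 and 5232 barcodes (KO), with 23861775, 20796916, 12408305 and 24480326 UMIs. The CD45- libraries held 5467 and 2389 barcodes (WT) and 149 and 3078 barcodes (KO), with 19464000, 16567045, 1294150 and 27499928 UMIs. Median UMIs per barcode ran from 2478 to 7537.5. The authors' tables keep 11982 CD45+ and 5467 CD45- cells. KO CD45- replicate 1 is the shallow library of the series, with 22 cells and 202583 UMIs in the keratin-expressing class and 69 barcodes with 428351 UMIs in whole CD45- sums and shares.

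The first question was whether the injected genotype shows in Ripk1 itself. In the keratin-expressing CD45- cells, Ripk1 stood at 15.3 and 12.5 CPM (UMIs scaled to the same library total) in the WT libraries, at 5.13 in KO replicate 2 (exact Poisson 95% interval 3.93 to 6.58), and at 0 of 202583 UMIs in KO replicate 1, which allows up to 14.8 CPM. Ripk1 fell by 1.83 ± 0.31 on the log2 scale (SE; edgeR adjusted p = 0.0199). Host cells carry their own Ripk1. In the order WT replicate 1, WT replicate 2, KO replicate 1, KO replicate 2, it stood at 39.5, 30.6, 34.0 and 49.0 CPM in monocytes and macrophages and at 38.1, 26.3, 24.7 and 32.8 in T cells. The same order gave 28.0, 25.9, 22.5 and 45.4 in NK cells, 36.9, 20.9, 21.4 and 52.8 in neutrophils and 39.9, 22.7, 20.9 and 30.9 in dendritic cells. Whole CD45+ sums had 39.0, 29.6, 30.1 and 45.7, and whole CD45- sums 14.2, 11.7, 2.33 and 6.31 (log2 fold change -1.57, edgeR adjusted p = 0.309). Ripk1 lies on chromosome 13 from 34002363 to 34037147 on the plus strand of GRCm38/mm10 and is annotated as protein-coding. The position of the edit is not given in the sources used here. A 3' tag can lie outside an edited exon, so the remaining Ripk1 UMIs of KO cells do not measure residual protein.

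**Figure D1:**
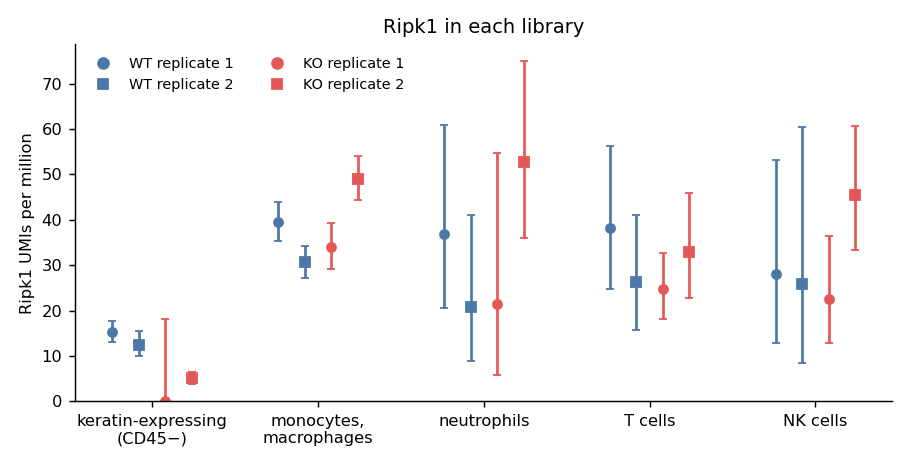
Ripk1 CPM (vertical axis) in each library, by cell class, with exact Poisson 95% intervals as bars. In keratin-expressing CD45- cells the WT libraries stood at 15.3 and 12.5 and the KO libraries at 0 and 5.13. The host classes shown stood between 21.4 and 52.8 in KO tumours.

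The sort was checked in sums over whole libraries. The genes were Ptprc, which encodes CD45, Krt8, a keratin of simple epithelia, and Epcam, an epithelial adhesion gene. In the order WT replicate 1, WT replicate 2, KO replicate 1, KO replicate 2, Ptprc stood at 1.21, 0.839, 39.7 and 1.59 CPM in CD45- barcodes within the limits and at 294, 308, 456 and 381 in kept CD45+ cells. KO CD45- replicate 1 thus held more Ptprc than the other CD45- libraries. Krt8 stood at 272, 235, 261 and 375 in the CD45- and at 4.58, 6.07, 4.03 and 4.81 in the CD45+ libraries. Epcam stood at 0, 6.46, 37.4 and 0.618 in the CD45- and at 2.57, 0.769, 3.81 and 4.39 in the CD45+ libraries. It thus did not separate the sorts. In the keratin-expressing class Epcam stood at 0, 0.872, 0 and 0.165 CPM, where the 0 of KO replicate 1 allows up to 14.8.

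The comparison of keratin-expressing CD45- cells was aimed at the injected cells, although the class also holds a cluster led by the muscle gene Acta1. Timp3, an inhibitor of metalloproteinases, fell 37.1-fold (log2 fold change -5.21 ± 0.33, SE, edgeR adjusted p = 0.00218), from 90.5 and 102 CPM in WT to 0 and 3.39 in KO. Pdgfrb, a receptor for platelet-derived growth factor, fell 7.63-fold, from 96.6 and 95.2 to 24.7 and 14.7. The collagen genes Col1a1 (-2.47 ± 0.25) and Col6a3 (-2.82 ± 0.26) fell as well. Genes that rose included Gas6, a ligand of TAM receptors (8.34-fold, from 4.07 and 3.63 CPM to 64.2 and 36.5), and Spp1, which encodes the secreted phosphoprotein osteopontin (5.10-fold, from 36.5 and 31.8 to 104 and 288). Gas6 is also among the leading genes of a macrophage cluster led by Ccl8 and Cd163, and RNA of macrophages was not separated from its value here. Without KO replicate 2 the log2 fold change was -2.04 for Pdgfrb, 3.96 for Gas6 and 1.52 for Spp1, and Spp1 was not called without WT replicate 1 (edgeR adjusted p = 0.0739). The remaining KO library then had 0 UMIs of Timp3 and Col6a3, so that no fold is given for these.

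edgeR called 772 of 10926 genes in these cells, 335 higher and 437 lower in KO. Among genes with a mean of at least 20 CPM and no overlap between genotypes, the others with the largest falls were Pla2g16, a phospholipase gene (-3.90 ± 0.44, edgeR adjusted p = 0.00603), Pcdh19, a protocadherin (-2.84 ± 0.28), and S100a16, a calcium-binding protein gene (-2.77 ± 0.26). By the same rule the others with the largest rises were Hspb6, a small heat shock protein (3.62 ± 0.85, edgeR adjusted p = 0.0437), Tmem158 (2.76 ± 0.24), Ddah2, which breaks down methylated arginine (2.11 ± 0.19), and Lgals7, a galectin (2.1 ± 0.21). Hspb6 stood at 21 and 22.2 CPM in WT and at 563 and 77.2 in KO, and its log2 fold change was 1.51 without KO replicate 1 and 4.62 without KO replicate 2. Without KO replicate 2, Pla2g16 had -1.29 (edgeR adjusted p = 0.484), S100a16 -2.14 (0.0738), Tmem158 2.08 (0.0946) and Lgals7 1.41 (0.267), none of them called, and Pcdh19 had 0 UMIs in the remaining KO library. KO replicate 1 had 3, 4, 11 and 7 UMIs of the 4 genes with values. Without WT replicate 1, Pla2g16 had -2.98 (0.246) and was not called. Timp3 lies on chromosome 10 from 86300372 to 86349506 and Hspb6 on chromosome 7 from 30552178 to 30555443, both on the plus strand.

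**Figure D2:**
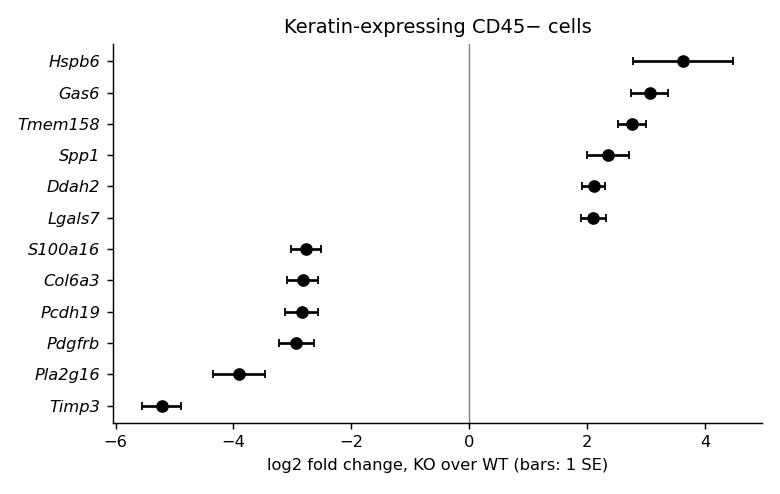
Log2 fold change, KO minus WT (horizontal axis, with 1 standard error), of the 12 genes with the largest called changes in keratin-expressing CD45- cells among genes with a mean of at least 20 CPM and no overlap between genotypes. Of these, Timp3 stood lowest at -5.21 and Hspb6 highest at 3.62.

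The cluster that held the most of these cells differed between WT and KO, and between the KO libraries. A cluster led by Npnt, Pdgfrb and Timp3 held 70.5% and 69.6% of the class in WT and 4.55% and 0.927% in KO. A cluster led by Cpe, Sox4, Cdkn2a and Tmem158 held 1.10% and 0.415% in WT and 27.3% and 86.1% in KO. Some of the genes named above thus also lead these clusters and are not independent of them. The cluster led by Acta1 held 8.59% and 15.3% in WT and 45.5% and 0.0662% in KO. For KO replicate 1 these shares rest on 1, 6 and 10 cells, in the order the clusters are given. Without that cluster edgeR called 1957 genes, among them 762 of the 765 genes still tested. Hbb-bs, a haemoglobin gene of red cells, stood at 222 CPM in KO replicate 1 and at 2.71 to 7.28 in the other libraries.

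Among genes of the fixed lists, the p53 target and cell cycle inhibitor Cdkn1a (-1.93 ± 0.24), the keratin Krt19 (-2.70 ± 0.30) and the matrix gene Thbs1 (-1.88 ± 0.22) fell. The viral RNA sensor Ifih1 (-2.37 ± 0.36), the interferon-stimulated Trim30a (-2.94 ± 0.46), the angiogenic factor Vegfa (-1.66 ± 0.33) and the hexokinase Hk2 (-2.05 ± 0.47) fell too. Vegfa is also among the leading genes of the cluster led by Acta1, so its value is not independent of that cluster's share. With 1 library left out Vegfa ran from -2.07 to -1.25. The matrix gene Tgfbi (1.87 ± 0.20), the p53 target Bbc3 (1.60 ± 0.30), the MHC class I gene H2-D1 (1.12 ± 0.25) and the chemokines Ccl8 (2.02 ± 0.33) and Cxcl2 rose. Ccl8 also leads a macrophage cluster, and RNA of macrophages was not separated from its value in the keratin-expressing cells. Cxcl2, a neutrophil attractant, had 3 UMIs in 17933210 in WT and 42 in 12287560 in KO, a ratio of 20.4 (95% counting interval 6.53 to 103), and 41 of the 42 came from KO replicate 2. Cxcl5, a related chemokine, passed the test (1.18 ± 0.26, edgeR adjusted p = 0.0387), but KO replicate 1 at 19.7 CPM lay below both WT libraries (26.7 and 22.0) while KO replicate 2 stood at 78.1. In the keratin-expressing cells of the CD45+ libraries Cxcl2 was lower in KO (-0.77), and without KO replicate 2 Cxcl5 was lower as well (-0.39). Without that library none of Trim30a (-0.61, edgeR adjusted p = 0.837), Hk2 (-0.96, 0.715), Krt19 (-1.25, 0.501), Thbs1 (-1.09, 0.276), Cdkn1a (-1.30, 0.403) and Bbc3 (2.45, 0.116) was called, and Ifih1 had 0 UMIs in the remaining KO library. KO replicate 1 had 1, 5, 2, 6, 3 and 7 UMIs of the other 6 genes in that order. Without WT replicate 2, Hk2 had -1.01 and was not called. Vldlr, a lipoprotein receptor gene, had 0 UMIs in KO and was at least 13-fold lower, with the floor taken over the group.

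No list as a whole was called by camera in these cells (0 of 19), but leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 5, 2, 2 and 5 called lists. The mesenchymal and matrix list had 1 member higher and 6 lower of 23 (adjusted over the list alone 2 and 6; median -0.31; camera adjusted p = 0.188). Chemokines had 3 higher and 1 lower of 17 (adjusted over the list alone 5 and 2; median 0.63; 0.145). The death receptor list, which holds Ripk1 itself, had 2 lower of 22 (adjusted over the list alone also 2; 0.295). Interferon-stimulated genes had 3 lower of 26 (adjusted over the list alone 4; 0.955), and camera ranked them higher although their median (-0.13) and mean (-0.30) were negative. For the remaining lists the camera adjusted p was 0.188 for IFN-gamma response and MHC class I, 0.150 for MHC class II, 0.150 for inflammatory macrophage genes, 0.188 for haemoglobin, 0.555 for cell cycle and 0.764 for dissociation-induced genes. It was 0.847 for NF-kB targets, suppressive myeloid genes, T cell activation, naive and memory T cell, p53 targets and the unfolded protein response, and 0.955 for regulatory T cell, hypoxia and epithelial genes. Median and mean differed in sign for hypoxia (0.14 and -0.01, camera lower), epithelial genes (0.14 and -0.29, camera higher) and p53 targets (-0.01 and 0.09, camera higher). Cytotoxic effectors had too few measured members. The unfolded protein list had a median of -0.14 with Vldlr either fitted or at its bound.

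The number of called genes in this class depended on single libraries. Leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 40, 120, 2959 and 290 calls, which held 14, 33, 772 and 50 of the 772. Of the called genes named for this class, Hspb6, Gas6, Timp3, Pdgfrb, Pcdh19, Col6a3 and Col1a1 stayed called whichever library was left out. Every other one, Ripk1 included, was not called without at least 1 library. DESeq2 called 99 genes, 22 higher and 77 lower, no low-count filter gave 368, and keratin-expressing cells of the CD45+ libraries gave 3, all lower. In simulated data with no changed gene this class gave 28 to 57 calls.

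In monocytes and macrophages of the CD45+ sort, which keep their own Ripk1, the question was how host cells differ when the cancer cells lack it. Cxcl13, a chemokine that attracts B cells, rose 16.5-fold, from 4.35 and 2.74 CPM in WT to 54.0 and 62.0 in KO (log2 fold change 4.04 ± 0.21, SE, edgeR adjusted p = 0.0394). It was the 1 gene called of 10961. At an unadjusted p under 0.05 there were 913 genes. By camera at the preset correlation, hypoxia and glycolysis genes were lower as a list in KO macrophages, and antigen presentation, interferon and cytotoxic genes were higher. None of these calls held with an estimated correlation (adjusted p from 0.492 to 0.674), and fry called 0 lists.

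The cluster built here that held the most cells of this class differed between genotypes and between the KO libraries. A cluster led by Mmp12, Arg1 and Hmox1, with Hilpda among its leading genes, held 40.4% and 62.5% of the class in WT and 4.76% and 8.80% in KO. The cluster led by Cxcl9, Fcgr4 and Iigp1, with class II genes among its leading genes, held 55.0% in KO replicate 1, 2.03% in KO replicate 2 and 0.559% and 0.639% in WT. Another, led by Ccl8, Cd163 and Mrc1, held 2.20% and 38.9% in KO and 7.74% and 4.47% in WT, and a cluster led by class II genes 36.1% and 18.8% in WT and 21.2% and 35.4% in KO. Arg1, Hmox1, Hilpda, Ccl8, Cxcl9, Iigp1 and class II genes thus also lead these clusters, and their values in the class are not independent of the clusters' shares.

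The hypoxia and glycolysis list had a median log2 fold change of -1.0, with 23 of 24 members lower (camera adjusted p = 2.61e-25, adjusted p = 0.492 with an estimated correlation). No member was called over all genes, and 16 were lower adjusted over the list alone. Ndrg1, induced under low oxygen, had -1.89 (edgeR adjusted p = 0.360) and the glucose transporter Slc2a1 -1.57 (0.447). The MHC class II list had a median of 1.65 with 10 of 10 members higher (8 adjusted over the list alone; camera adjusted p = 1.45e-12, adjusted p = 0.508 with an estimated correlation). H2-Aa, a class II alpha chain, had 1.69 (edgeR adjusted p = 0.513), H2-DMb1, which helps to load class II, 1.96 (0.512), and Ciita, the class II transactivator, 1.69 (0.513). IFN-gamma response and MHC class I genes were higher in 29 of 29 members (median 1.17; camera adjusted p = 2.26e-16, adjusted p = 0.673 with an estimated correlation), and Iigp1, an interferon-inducible GTPase, had 2.37. Interferon-stimulated genes were higher in 30 of 31 (median 0.58; 1.07e-07, adjusted p = 0.674 with an estimated correlation), with Ifi47 at 1.39 and Eif2ak2 at 0.74. Neither interferon list had a member called, over all genes or adjusted over the list alone. Without KO replicate 1, Iigp1 had 1.05, Ifi47 0.44, H2-DMb1 1.27 and H2-Aa 1.10, and without KO replicate 2 Iigp1 had 3.06. A fit without 1 KO library has no spread between KO tumours, so calls from such fits are not read as support for these genes.

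Cytotoxic effector genes were higher in 16 of 16 measured members (median 1.76; 7 adjusted over the list alone; camera adjusted p = 1.25e-23, adjusted p = 0.492 with an estimated correlation). The members with the smallest p were granzymes: Gzmf stood at 0.114 and 0.507 CPM in WT and at 17.9 and 13.3 in KO macrophages, and Gzmd had a log2 fold change of 4.42 (edgeR adjusted p = 0.258 for both). In NK cells of the same libraries Gzmf stood at 77.8, 1245, 216 and 2213 and Gzmd at 486, 1650, 317 and 1603. In this macrophage class, 6 cells of the KO libraries and 0 of WT lay in a cluster led by Gzmc, Gzma and Ncr1, and 2 and 0 in a cluster led by T cell receptor genes. RNA of NK and T cells was not separated from the cytotoxic and T cell values of macrophages. T cell activation genes were higher in 11 of 12 (median 0.64; adjusted over the list alone 3 higher and 1 lower; 0.000918, adjusted p = 0.492 with an estimated correlation). Suppressive myeloid genes were lower in 14 of 23 (median -0.23; adjusted over the list alone 5 lower and 2 higher; 0.000255, adjusted p = 0.492 with an estimated correlation). Arg1, the arginase of alternatively activated macrophages, stood at 983 and 1220 CPM in WT and at 180 and 164 in KO (log2 fold change -2.67, edgeR adjusted p = 0.247). Spp1 had -2.02 (0.360), and Hmox1, which degrades haem, -1.07 (0.512). With 1 library left out Arg1 ran from -2.89 to -2.43, Spp1 from -2.36 to -1.72, Gzmf from 4.84 to 6.97 and Gzmd from 3.93 to 4.82. Arg1 and Hmox1 lead the cluster that held 40.4% and 62.5% of the class in WT and 4.76% and 8.80% in KO.

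**Figure D3:**
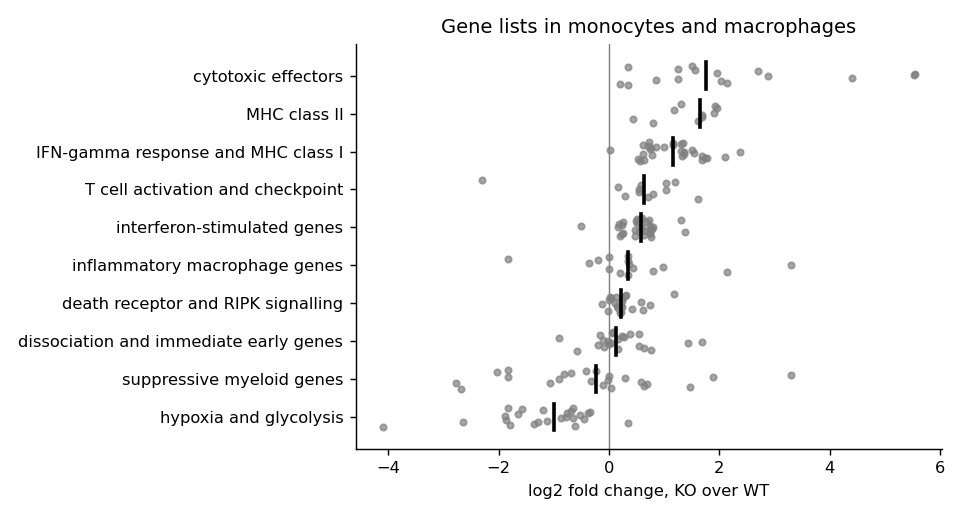
Log2 fold change, KO minus WT (horizontal axis), of each measured member (points) of the 10 lists that camera called in monocytes and macrophages, with the median as a black line. The hypoxia list has its median at -1.0 and the cytotoxic list at 1.76.

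Smaller shifts were seen for death receptor genes (20 of 22 higher, median 0.21; camera adjusted p = 0.00895, adjusted p = 0.674 with an estimated correlation), inflammatory macrophage genes (11 of 15 higher, median 0.35; 0.0152, adjusted p = 0.707 with an estimated correlation) and dissociation-induced genes (14 of 22 higher, median 0.12; 0.0225, adjusted p = 0.674 with an estimated correlation). Leaving out 1 library ended these and the interferon-stimulated call. The camera adjusted p was 0.0923 without WT replicate 2 and 0.192 without KO replicate 1 for death receptor genes. For inflammatory genes it was 0.101 without WT replicate 1 and 0.663 without KO replicate 1, and for dissociation-induced genes 0.776 and 0.130 in the same order. It was 0.431 without KO replicate 1 for interferon-stimulated genes. Not called were NF-kB targets (0.878), chemokines, naive and memory T cell, epithelial, mesenchymal and p53 target genes (0.846 each), regulatory T cell (0.159), cell cycle (0.810) and unfolded protein genes (0.185). The mesenchymal list had a median of -0.01 and a mean of 0.14, NF-kB targets 0.01 and -0.03.

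Chemokine genes with the smallest p in macrophages were Ccl8, a monocyte attractant, at 1342 and 766 CPM in WT and 5803 and 9856 in KO (edgeR adjusted p = 0.266), Cxcl3, a neutrophil attractant, with -3.01 (0.266), and Cxcl9, an IFN-gamma-induced T cell attractant, with 3.31 (0.513). Cxcl9 had 1.81 without KO replicate 1 and 4.03 without KO replicate 2. With 1 library left out Ccl8 ran from 2.59 to 3.26 and Cxcl3 from -3.51 to -2.52. Leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 4, 0, 179 and 570 calls in this class, and DESeq2 called 95 genes (53 higher and 42 lower). Without WT replicate 2, and without the barcodes of the top 6% of doublet scores, Cxcl13 was not called.

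Neutrophils, called Neutrophil/MDSC by the authors, had 4 called genes of 4606. The chemokines Ccl8 and Cxcl13 rose and Cxcl3 and Hilpda, a hypoxia-inducible lipid droplet gene, fell. Ccl8 stood at 760 and 535 CPM in WT and at 5386 and 8163 in KO (log2 fold change 3.34 ± 0.34, SE, edgeR adjusted p = 0.00752). Cxcl13 had 0 of 790145 UMIs in WT and 61 of 773958 in KO and was at least 20.8-fold higher, with the floor taken over the group (edgeR adjusted p = 0.0256). Cxcl3 changed by -4.15 ± 0.49 (0.0140) and Hilpda by -4.04 ± 0.52 (0.0233). The hypoxia list was lower in 20 of 20 members (median -1.0; 7 adjusted over the list alone; camera adjusted p = 1.68e-13). IFN-gamma response genes were higher in 24 of 24 (median 0.93; none adjusted over the list alone; 5e-13), interferon-stimulated genes in 22 of 25 (0.84; none; 6.26e-11) and MHC class II genes in 6 of 7 (1.5; 6; 7.74e-09). Cytotoxic effectors (4 of 6 higher, median 1.05, 2 adjusted over the list alone; 0.00338), mesenchymal genes (3 of 5 lower, median -0.66, 1; 0.00338) and suppressive myeloid genes (12 of 18 lower, median -0.38, adjusted over the list alone 7 lower and 3 higher; 0.0447) were called too. For all 7 lists the adjusted p = 0.590 with an estimated correlation. Suppressive genes were not called without WT replicate 2 (0.636), KO replicate 1 (0.152) or KO replicate 2 (0.0702), nor mesenchymal genes without WT replicate 1 (0.149). Leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 73, 32, 2 and 92 called genes, and without KO replicate 1 Ccl8 was the 1 of the 4 still called. Hilpda had -5.32 without KO replicate 2, with 2 UMIs in the remaining KO library. DESeq2 called 3 genes and not Cxcl13. KO replicate 1 holds 32 of these cells.

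In macrophages of the same libraries the 4 called genes had changes of the same sign, but Cxcl13 alone was called there (edgeR adjusted p = 0.266 for Ccl8 and Cxcl3 and 0.347 for Hilpda). Ccl8 stood at 5803 and 9856 CPM and Cxcl13 at 54.0 and 62.0 in KO macrophages, and Cxcl3 and Hilpda had -3.01 and -3.02. The macrophage gene C1qa, chosen after its values were seen, stood at 2626, 1747, 4344 and 3845 CPM in neutrophils and at 5121, 3998, 5892 and 6357 in macrophages, in the order WT replicate 1, WT replicate 2, KO replicate 1, KO replicate 2. In that order a cluster led by G0s2 and S100a9, in which 8 macrophage markers were detected, held 69.5%, 28.1%, 43.8% and 64.2% of the class. Another, led by S100a8 and S100a9, held 8.54%, 49.4%, 15.6% and 13.2%. RNA of macrophages was not separated from the neutrophil values.

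T cells had 14 called genes of 6809, all lower in KO, in 2 kinds. Of these, 7 were more abundant in WT T cells than in monocytes and macrophages, osteoclast-gene cells and NK cells. Cd163l1, a scavenger receptor gene of gamma-delta T cells, fell from 168 and 199 CPM to 17.0 and 17.4 (log2 fold change -3.40 ± 0.26, SE, edgeR adjusted p = 0.0102). The Src-family kinase Blk (-3.32 ± 0.37), the leukotriene B4 receptor Ltb4r1 (-3.00 ± 0.41) and the gamma receptor constant gene Tcrg-C1 (-2.45) fell with it. The other 7 were more abundant in another type. They included Arg1 (75 UMIs of 1378545 in WT and 3 of 2977571 in KO, a ratio of 0.0185 with a 95% counting interval of 0.00374 to 0.0562), the bone-resorption genes Ctsk (-3.76 ± 0.50) and Acp5 (-2.73), and the metalloproteinase Mmp9 (-3.49 ± 0.48). Acp5 stood at 715 CPM in WT T cells and at 7587 in the WT CD45+ cells that express osteoclast genes, and Ctsk at 405 and 4762. Without KO replicate 1, Ctsk had -3.12, Mmp9 -2.69 and Blk -3.93, without KO replicate 2 Ctsk had -4.68 and Mmp9 -4.72, and without WT replicate 2 Ltb4r1 had -2.41. Arg1 had -5.57 with all libraries and ran from -6.32 to -4.63 with 1 library left out. Tcrg-C1 and Acp5 were chosen after their values were seen.

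Interferon-stimulated genes were higher in 26 of 26 members in KO T cells (median 0.80; 10 adjusted over the list alone; camera adjusted p = 1.69e-15, adjusted p = 0.374 with an estimated correlation). IFN-gamma response genes were higher in 25 of 27 (0.50; 7 adjusted over the list alone; 1.32e-11, adjusted p = 0.209 with an estimated correlation), T cell activation genes in 12 of 15 (0.43; none; 0.00534, adjusted p = 0.429 with an estimated correlation) and cytotoxic effectors in 14 of 19 (0.60; none; 0.00534, adjusted p = 0.744 with an estimated correlation). Ccl5, a chemokine of effector T cells, had 0.96 (edgeR adjusted p = 0.341) and the checkpoint receptor Lag3 1.03 (0.669). Lag3 had 0.49 without KO replicate 1 and 1.82 without WT replicate 1. Lower were suppressive myeloid genes (11 of 13, median -0.48, 5 adjusted over the list alone; 2.31e-09, adjusted p = 0.209 with an estimated correlation), mesenchymal genes (5 of 5, -0.84, 1; 1.23e-05, adjusted p = 0.246 with an estimated correlation), hypoxia genes (16 of 20, -0.44, none; 0.00229, adjusted p = 0.649 with an estimated correlation) and chemokines (7 of 12, -0.43, adjusted over the list alone 5 lower and 1 higher; 0.00534, adjusted p = 0.649 with an estimated correlation). The macrophage genes Trem2 and C1qc and the MHC class II chaperone Cd74, chosen after their values were seen, had -3.36, -1.47 and -1.11 in T cells. The osteoclast-gene cluster led by Mt3, Mmp9 and Ctsk held 9 and 2 T cells of WT replicates 1 and 2 and none of KO, and that led by Bdh2, Fxyd2 and Jdp2 held 4 and 1 in WT and 0 and 1 in KO. RNA or cells of other types were not separated from these lower lists.

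Several T cell calls rested on single libraries. The cytotoxic list turned to lower without WT replicate 2 (camera adjusted p = 0.298) and without KO replicate 1 (0.230), and the chemokine list turned to higher without WT replicate 1 (0.902). T cell activation was not called without WT replicate 2 (0.295), nor hypoxia without KO replicate 1 (0.230). Leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 36, 39, 132 and 247 called genes, each set with all 14. Among T cells with at least 1000 UMIs edgeR called 0 genes (450 at an unadjusted p under 0.05), without the top 6% of doublet scores 3, and DESeq2 called 29.

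NK cells had 8 called genes of 5173. Gzma, the granzyme of resting NK cells, rose from 1713 and 1863 CPM to 5877 and 5681 (log2 fold change 1.68 ± 0.18, SE, edgeR adjusted p = 0.0160), and the chemokine Ccl4 from 68.5 and 77.8 to 284 and 283 (1.96 ± 0.24, 0.0276). Mmp9 (-3.22 ± 0.46), the chemokine Ccl1 (-2.63 ± 0.33), the stress gene Gadd45g (-2.28 ± 0.23), the cell cycle inhibitor Cdkn1a (-2.16 ± 0.32), Hilpda (-2.14 ± 0.28) and the cell cycle kinase Cdk6 (-1.55 ± 0.22) fell. Gzmc, another granzyme, had -1.17 (edgeR adjusted p = 0.182) and ran from -1.47 to -0.797 with 1 library left out. Hypoxia genes were lower in 15 of 16 members (median -0.80; 8 adjusted over the list alone; camera adjusted p = 1.3e-11), NF-kB targets in 14 of 18 (-0.72; 1; 4.17e-06) and MHC class II genes in 5 of 5 (-1.02; 2; 4.17e-06). Interferon-stimulated genes were higher in 18 of 19 (0.83; adjusted over the list alone 8 higher and 1 lower; 2.68e-10), IFN-gamma response genes in 24 of 25 (0.43; none; 1.84e-06), inflammatory genes in 4 of 5 (0.77; 2; 9.44e-06) and naive and memory T cell genes in 5 of 6 (0.77; 3; 0.000145). Suppressive myeloid (6 of 8 lower, 0.0278), regulatory T cell (4 of 5, 0.0327), p53 target (4 of 7, 0.0247) and unfolded protein genes (12 of 14, 0.0158) were lower as lists, with 1 p53 target called, Cdkn1a. For all of these the adjusted p = 0.258 with an estimated correlation. Cytotoxic effectors were higher in 11 of 18 (median 0.54; adjusted over the list alone 3 higher and 1 lower; 0.000225, adjusted p = 0.381 with an estimated correlation) and dissociation-induced genes in 15 of 21 (0.20; adjusted over the list alone 3 and 1; 0.0141, adjusted p = 0.291 with an estimated correlation).

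Leaving out WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 gave 10, 48, 47 and 0 called genes in NK cells, which held 3, 8, 8 and 0 of the 8. Without WT replicate 1, Ccl4, Gzma, Mmp9, Ccl1 and Cdk6 were not called, and RLE scaling gave 5 calls, 2 higher and 3 lower, against 2 and 6. WT replicate 2 holds 47 NK cells. Mmp9 had -4.59 without KO replicate 2, with 3 UMIs in the remaining KO library, and stood at 113 CPM in WT NK cells, against 1705 in WT osteoclast-gene cells. The osteoclast genes Acp5 (-3.13, edgeR adjusted p = 0.460) and Ctsk (-3.65) and the macrophage gene C1qa (-1.64, 0.460) were lower in KO NK cells as well, and none of these was called. Of the NK cells of WT replicate 1, 5 lay in a cluster led by Mt3, Mmp9 and Ctsk, and 0 in the other libraries. The macrophage cluster led by Mmp12, Arg1 and Hmox1, with Hilpda among its leading genes, held 3 and 1 NK cells of WT replicates 1 and 2 and 0 of KO. RNA or cells of these kinds were not separated from the values of Mmp9 and Hilpda in NK cells. The same holds for the hypoxia, suppressive myeloid and MHC class II lists. Acp5, Ctsk and C1qa were chosen for NK cells after their values were seen. Without WT replicate 1 the cytotoxic list turned to lower (camera adjusted p = 0.918), and suppressive myeloid (0.0839), naive and memory T cell (0.0938), p53 target (0.0938) and dissociation-induced genes (0.0664) were not called. Regulatory T cell genes were not called without WT replicate 2 (0.225), KO replicate 1 (0.178) or KO replicate 2 (0.172). P53 targets were lost without WT replicate 2 (0.225) and KO replicate 1 (0.379), and unfolded protein genes without WT replicate 2 (0.225), KO replicate 1 (0.0603) and KO replicate 2 (0.0565).

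Sums over whole CD45+ libraries mix the makeup of the sort with changes inside cells. Of 11707 genes edgeR called 5. Cxcl13 (3.76 ± 0.23, SE, edgeR adjusted p = 0.0434) and Gzma (3.41 ± 0.25, 0.0434) rose, and Cxcl3 (-3.65 ± 0.27, 0.0434), Arg1 (-3.06 ± 0.24, 0.0464) and the collagen gene Col14a1 (-3.06 ± 0.20, 0.0434) fell. Cytotoxic effectors were higher in 20 of 20 members (median 1.79; 16 adjusted over the list alone; camera adjusted p = 2.02e-26, adjusted p = 0.220 with an estimated correlation) and hypoxia genes lower in 24 of 24 (-1.0; 19 adjusted over the list alone; 8.42e-23, adjusted p = 0.402 with an estimated correlation). Lists of T cell activation (1.06e-17, adjusted p = 0.220 with an estimated correlation), regulatory T cell (3.26e-09, adjusted p = 0.264 with an estimated correlation) and naive and memory T cell (7.2e-07, adjusted p = 0.402 with an estimated correlation) were higher. So were IFN-gamma response (1.85e-14, adjusted p = 0.473 with an estimated correlation), MHC class II (3.84e-07, adjusted p = 0.443 with an estimated correlation) and interferon-stimulated genes (4.61e-05, adjusted p = 0.519 with an estimated correlation). Suppressive myeloid (8.93e-07, adjusted p = 0.443 with an estimated correlation) and mesenchymal genes (0.0367, adjusted p = 0.402 with an estimated correlation) were lower. Leaving out WT replicate 2, KO replicate 1 or KO replicate 2 gave 0, 123 and 966 called genes, and leaving out WT replicate 1 gave 5, with Cxcl3 the 1 of the named 5 among them. DESeq2 called 325, and all barcodes within the limits gave 0. Cxcl13 lies on chromosome 5 from 95956951 to 95961068 and Gzma on chromosome 13 from 113093825 to 113100981. Arg1 lies on chromosome 10 from 24915221 to 24927484, on the minus strand like Gzma.

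Over whole CD45- libraries edgeR called 0 of 12113 genes (1609 at an unadjusted p under 0.05) and DESeq2 230. KO replicate 1 enters with 69 barcodes, 43.5% of them in Ptprc-expressing clusters (exact binomial 95% interval 31.6% to 56.0%) against 0.870% to 1.29% in the other libraries. Lists of leukocyte and red cell genes were higher in KO by camera. These were MHC class II (6 of 6, median 4.83, 5 adjusted over the list alone; 0.00567), cytotoxic effectors (7 of 9, 5.29, none; 0.00884) and haemoglobin (4 of 4, 5.23, 4; 0.0146). Called as well were chemokines (0.00884), IFN-gamma response (0.00493), interferon-stimulated (0.0445), mesenchymal (0.0165), p53 target (0.0448) and dissociation-induced genes (0.00493). For all 9 lists the adjusted p = 0.847 with an estimated correlation. Without KO replicate 1 edgeR called 2591 genes and camera 3 lists, and interferon-stimulated (camera adjusted p = 0.107) and IFN-gamma response genes (0.472) turned to lower. Without KO replicate 2 edgeR called 1110 genes. In simulated data of this comparison 14% of 4-fold changes were recovered with a spread that differed from gene to gene. Where the spread followed a trend on the mean, 35.3% were recovered. At the geometric mean depth for all libraries, with the gene-to-gene spread, 0% were recovered.

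The makeup of the CD45+ sort was compared by the authors' cell types, as shares of kept cells. NK cells made up 3.5% and 2.1% of kept cells in WT and 10.9% and 12.0% in KO, a mean of 2.80% ± 0.992 against 11.5% ± 0.825 (SD, n = 2), or 4.08-fold. The exact binomial 95% intervals were 2.99% to 4.07% and 1.55% to 2.78% in WT and 9.48% to 12.4% and 11.0% to 13.2% in KO, for counting error only. With an edgeR adjusted p = 0.0513 over the 7 types, NK cells were not called. The type the authors name mpDC stood at 0.623% ± 0.122 and 2.04% ± 0.258 (adjusted p = 0.0513 by edgeR). Monocytes and macrophages stood at 76.9% ± 0.0134 and 53.8% ± 8.48 (edgeR adjusted p = 0.424), T cells at 11.4% ± 2.05 and 23.8% ± 12.3 (0.284), dendritic cells at 4.39% ± 1.47 and 5.10% ± 2.12 (0.720), neutrophils at 3.75% ± 0.320 and 3.18% ± 1.99 (0.720) and B cells at 0.167% ± 0.206 and 0.583% ± 0.824 (0.617). B cells were 0 of 3288 in KO replicate 2, which allows up to 0.0912%. Without KO replicate 1 the B cell difference turned to -5.13 and the neutrophil difference to 0.30 on the log2 scale. The dendritic cell difference turned to -0.09 without WT replicate 2, -0.30 without KO replicate 2 and -0.14 with TMM factors. For T cells the difference ran from 0.41 to 1.52 on the log2 scale with 1 library left out.

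**Figure D4:**
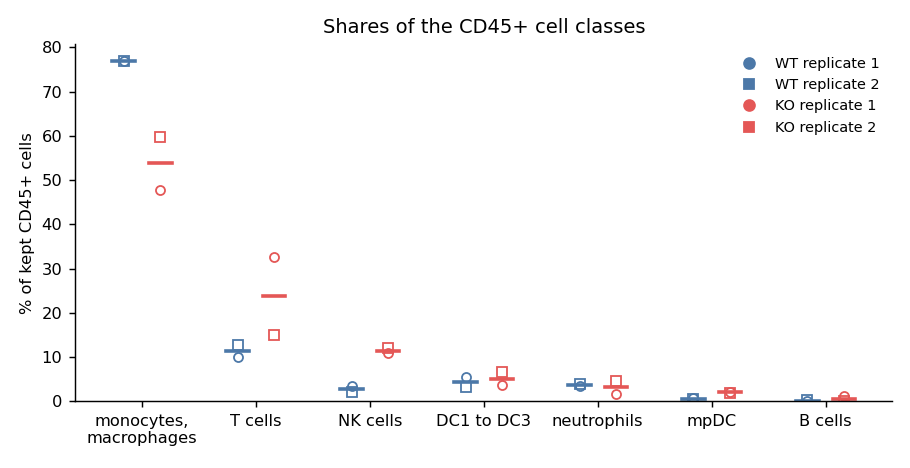
Share of kept CD45+ cells (vertical axis, percent) in each of the 7 cell types, with a point per library and a line at each genotype mean. NK cells stood at 3.5% and 2.1% in WT and at 10.9% and 12.0% in KO libraries.

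edgeR called 0 of the 7 types, with 2 at an unadjusted p under 0.05. limma on arcsine shares called 2 (NK cells, and monocytes and macrophages, both adjusted p = 0.0176), and over all barcodes within the limits edgeR called 2, NK cells (0.0315) and mpDC (0.0376). Of the 18 authors' clusters edgeR called 0 (3 at an unadjusted p under 0.05). The macrophage cluster Mac_4 stood at 15.7% ± 8.89 in WT and 2.78% ± 0.16 in KO (SD, n = 2; edgeR adjusted p = 0.154). Its log2 ratio was -2.50 and ran from -2.99 to -1.77 with 1 library left out. The CD8 T cell cluster CD8_1 had an adjusted p = 0.214 by edgeR, and its difference turned to -0.87 without KO replicate 1.

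Among CD45- barcodes within the limits edgeR called 0 of 6 cell classes (0 at an unadjusted p under 0.05; 1 without KO replicate 2). Keratin-expressing cells made up 90.1% ± 3.15 in WT and 63.3% ± 44.4 in KO (SD, n = 2), and Ptprc-expressing cells 1.01% ± 0.203 and 22.4% ± 29.8 (edgeR adjusted p = 0.364). Without KO replicate 1 the keratin difference turned to 0.07 on the log2 scale, and without KO replicate 2 the Ptprc-expressing class was called (5.42, adjusted p = 0.0225). Endothelial cells stood at 2.15% ± 0.694 in WT and 1.72% ± 1.67 in KO (SD, n = 2), with 2.90% and 0.539% in KO replicates 1 and 2. Fibroblasts stood at 1.05% ± 0.407 and 4.21% ± 2.25, with 5.80% and 2.62% in KO. The values of KO replicate 1 rest on 2 endothelial cells and 4 fibroblasts among 69 cells. The sort removes CD45+ cells, so these shares describe what passed the gate.

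Whether the KO effect differed between cell classes was tested directly. Between monocytes and macrophages and T cells, 28 of 10918 genes differed, 27 with the more positive change in macrophages, and 684 had an unadjusted p under 0.05. Between keratin-expressing cells and monocytes and macrophages, 10 of 12239 genes differed, 3 more positive in keratin-expressing cells (Dbn1, Cxcl2 and Spp1) and 7 more negative. The sorts share tumours, and with the tumour as a block, taken from equal replicate numbers, 325 genes differed, 165 more positive and 160 more negative. Among these 7 was the inflammatory caspase Casp4 (-3.84). Dbn1 and Casp4 were chosen after their values were seen.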

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

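Of the tests in this part, those of free RNA and of other abundant transcripts were chosen after the result was seen, and the test of whole cells of another type before.

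The KO effect differed between monocytes and macrophages and T cells for 28 genes by a test of the difference itself. H2-Aa differed by 2.19 on the log2 scale (1.69 in macrophages and -0.50 in T cells), the bone-resorption gene Ctsk by 2.89 (-0.60 and -3.76) and the leukotriene receptor Ltb4r1 by 3.12 (0.16 and -3.00). Cd74 differed by 2.74 (1.61 and -1.11), the complement gene C1qc by 1.97 (0.54 and -1.47) and the lipid receptor Trem2 by 2.95 (-0.42 and -3.36). The tetraspanin Cd9 was the 1 gene with a negative difference (-1.74). RNA or cells of other types were not separated from the T cell values that enter these differences. The test was repeated with RLE scaling and with no low-count filter, but not with a library left out or without high doublet scores. Cd74, C1qc, Trem2 and Cd9 were named after their values were seen, and so were Acp5, Ccl9, Ckb and Avpi1 below.

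The first pattern weighed was that macrophage and osteoclast genes (Acp5, Ctsk, Mmp9, Arg1, Ccl9, Ckb and Avpi1) were lower in KO T cells. Free RNA of other cells may add to it, since the 5 of these 7 genes that were tested in NK cells had a median of -3.13 there, but it does not account for the whole, because the richest 5% of WT T cells held 68.1% and 70.5% of these UMIs against 16.5% and 18.0% if evenly spread. For the presence of these UMIs in WT T cells, a candidate explanation that the values go with is doublets or misplaced whole cells, with a mean ratio of 4.02 to even spreading. The same 23 and 14 cells also held at least 4.46 times their even share of 20 other abundant transcripts of osteoclast-gene cells, with median doublet scores of 0.194 and 0.174 against 0.0192 and 0.0144 over all T cells. Both tests covered WT T cells only, so they do not show why the genes were lower in KO. Osteoclast-gene cells made up 41.5% and 29.7% of WT and 8.42% and 32.9% of KO barcodes. With KO replicate 2 as the remaining KO library, Ctsk still had -3.12 and Mmp9 -2.69 in T cells. A difference inside T cells that the genotype brings stays open and was not tested.

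Between keratin-expressing CD45- cells and monocytes and macrophages the KO effect differed for 10 genes, again by a test of the difference, and for 325 genes with the tumour as a block. Spp1 rose in keratin-expressing cells (2.35) and had -2.02 in macrophages, a difference of 4.38. Cxcl2 had 3.94 and -0.92, a difference of 4.91, which rests in keratin-expressing cells on 3 UMIs in WT and 42 in KO (ratio 20.4, 95% counting interval 6.53 to 103).

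A signal in data outside the comparisons came from a pair of cell groups. In the CD45+ libraries, 5592 barcodes in 4 clusters called osteoclast-gene cells here were left out of the authors' annotation. The rule, set after the data had been seen, took clusters with at least 1000 CPM of Acp5, 500 of Ctsk, over 5 of Ptprc and under 50% of their cells kept by the authors. The last condition kept out a pair of clusters with more of both genes (Acp5 2695 and 4520, Ctsk 1701 and 2967 CPM) than the cluster of cell cycle genes that was taken in (1597 and 880). Of these a cluster led by G0s2 and S100a9 had 268 of 284 cells kept and held 1.63% and 0.897% of WT and 0.681% and 2.22% of KO barcodes, and a cluster led by F13a1 and Mrc1 had 268 of 445 kept and held 3.28% and 1.51% of WT and 0.389% and 2.54% of KO barcodes. Osteoclast-gene cells, kept or not, made up 41.5% and 29.7% of WT and 8.42% and 32.9% of KO barcodes within the limits. Keratin-expressing cells in the CD45+ libraries numbered 272, or 1.04% and 0.352% of WT and 3.21% and 2.22% of KO barcodes, and none was in the authors' table.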

How the results depend on the processing

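The alternatives on doublet scores, on all barcodes within the limits and on which keratin-expressing cells were used were chosen after seeing the data, and the others before the data were examined. Over all genes, lists and shares chosen by the fixed rules and all settings, 1579 fold changes of named genes stayed on their side of the threshold with the same direction, 225 were no longer called, 141 became called and 21 changed sign. For lists these numbers were 624, 152, 51 and 81, for shares 283, 0, 5 and 29. Of the counts of calls, 92 lay within 1.5 times the reported count and 75 did not. KO CD45- replicate 1 has 202583 UMIs in 22 keratin-expressing cells, so a gene with 0 UMIs there can stand at up to 14.8 CPM. Except where fewer libraries or more genes were tested the cause was not tested. A lone library left in an arm was assumed to vary like the other group.

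With DESeq2 the counts were 99 in keratin-expressing cells, 95 in monocytes and macrophages, 29 in T cells, 325 in whole CD45+ and 230 in whole CD45- libraries. With no low-count filter they were 368 in keratin-expressing cells, 5 in monocytes and macrophages, 57 in neutrophils, 237 in T cells, 105 in NK cells and 113 in whole CD45+ libraries, and 219 and 24 for the differences of macrophages from T cells and of keratin-expressing cells from macrophages. RLE scaling gave 5 in NK cells. Cells with at least 1000 UMIs gave 0 in T cells by edgeR (450 at an unadjusted p under 0.05) and 23 in whole CD45+ libraries. By edgeR, removal of the top 6% of doublet scores gave 0 in monocytes and macrophages (942 at an unadjusted p under 0.05), 3 in T cells, 4 in NK cells and 0 in whole CD45+ libraries (1496). All barcodes within the limits gave 0 in whole CD45+ libraries (1341), keratin-expressing cells without the Acta1 cluster 1957, and those of the CD45+ libraries 3. Shares gave 2 calls among CD45+ types by limma on arcsine values and 2 over all barcodes within the limits, against 0 by edgeR (2 at an unadjusted p under 0.05). Camera with an estimated correlation and fry each called 0 lists in monocytes and macrophages (1 and 2 at an unadjusted p under 0.05), neutrophils (0 and 0), T cells (3 and 3), NK cells (0 and 3), whole CD45+ (3 and 3) and whole CD45- libraries (0 and 0).

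With 1 library left out, edgeR counts of genes ranged from 40 (without WT replicate 1) to 2959 (without KO replicate 1) in keratin-expressing cells and from 0 (without WT replicate 2, 249 at an unadjusted p under 0.05) to 570 (without KO replicate 2) in monocytes and macrophages. They ranged from 2 (without KO replicate 1) to 92 (without KO replicate 2) in neutrophils, 36 (without WT replicate 1) to 247 (without KO replicate 2) in T cells and 0 (without KO replicate 2, 268 at an unadjusted p under 0.05) to 48 (without WT replicate 2) in NK cells. In whole CD45+ libraries the range was 0 (without WT replicate 2, 562) to 966 (without KO replicate 2), and in whole CD45- libraries 0 (without WT replicate 1, 278, or 2, 329) to 2591 (without KO replicate 1). Counts of lists ranged from 2 to 5 in keratin-expressing cells and from 3 to 12 in whole CD45- libraries, and counts of CD45- shares from 0 to 1.

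Among the genes and shares given in the text as differences between genotypes, not as levels alone, those that changed sign were Cxcl2 in keratin-expressing cells taken from the CD45+ libraries (-0.77), Cxcl5 in keratin-expressing cells without KO replicate 2 (-0.39, up to 1.35 with another library left out) and the dendritic cell share with TMM factors (-0.14), without WT replicate 2 (-0.09) and without KO replicate 2 (-0.30, up to 0.61 with another left out). Without KO replicate 1 the B cell (-5.13, range to 4.48), neutrophil (0.30, range from -1.07), CD8_1 (-0.87, range to 5.07) and CD45- keratin (0.072, range from -1.50) shares changed sign. Of the lists called in their class, those that changed direction were chemokines in T cells (camera adjusted p = 0.902 without WT replicate 1, lowest 1.17e-14), cytotoxic effectors in T cells (0.298 without WT replicate 2, 0.230 without KO replicate 1, lowest 2.09e-11) and in NK cells (0.918 without WT replicate 1, lowest 6.46e-09), and in whole CD45- libraries without KO replicate 1 interferon-stimulated (0.107, lowest 1.51e-07) and IFN-gamma response genes (0.472, lowest 3.27e-13).

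Within a sort, WT and KO libraries of equal replicate number gave no sign of being paired. The correlation of deviations between equal numbers ran from -0.248 in whole CD45- libraries to 0.000117 in keratin-expressing cells. A single correlation per class cannot exclude a shared batch, and it does not bear on whether equal numbers in the 2 sorts mark the same tumour. With the replicate number as a block, edgeR called 305 genes in keratin-expressing cells, 2 in monocytes and macrophages, 23 in neutrophils, 3 in T cells, 102 in whole CD45+ and 11 in whole CD45- libraries, and camera called 5 lists in keratin-expressing cells. With the tumour as a block, 325 genes differed between keratin-expressing cells and macrophages.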

Other observations

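Of the tests in this part, those of free RNA in macrophages, of free RNA for Cd163l1, Blk, Tcrg-C1 and Serpinb1a, of the share of gamma-delta type cells, of the small KO library and of the Acta1 cluster were chosen after the result was seen, and the others before. The tests of the cluster led by Mmp12, Arg1 and Hmox1 and of how evenly gamma-delta genes were spread were added late, with bounds set before their values were seen.

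In keratin-expressing CD45- cells Xist, the RNA that coats the inactive X chromosome of female cells, stood at 1.36 and 5.23 CPM in WT and at 0.248 in KO replicate 2, against 873 to 1218 in monocytes and macrophages. In these 3 CD45- libraries the class is the cells that the authors kept, by rules that are not given in the sources used here. In KO replicate 1 the class was defined here by clusters with low Xist, so that its level is not given. Cdkn2a, which encodes cell cycle inhibitors, stood at 471 and 575 CPM in WT and 1728 and 1248 in KO keratin-expressing cells (log2 fold change 1.31 ± 0.31, SE, edgeR adjusted p = 0.0469). Xist, Cdkn2a and the genes of the next paragraph were chosen after their values were seen.

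Macrophage clusters built here were uneven between the KO tumours. The cluster led by Cxcl9 and Iigp1 had 484 of its 558 CD45+ barcodes in KO replicate 1. A cluster led by Ccl8, Cd163 and the mannose receptor gene Mrc1 had 769 of its 1146 in KO replicate 2, or 15.3% of that library against 0.925% in KO replicate 1. In WT macrophages Hbb-bs had 1108 UMIs, against 3 in KO, a ratio of 0.00377 (95% counting interval 0.000776 to 0.0110), but the gene was not called (edgeR adjusted p = 0.545), and WT replicate 2 stood at 111 CPM against 1.72 in WT replicate 1.

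The second pattern weighed was the lower hypoxia and glycolysis list in KO macrophages. A single library as the cause is argued against by a median of -0.63 or lower whichever library was left out, and a smaller share of the authors' cluster Mac_4 by a median of -0.79 without its cells, against -1.05 with them in the same calculation. Free RNA of other cells and a change inside macrophages cannot be told apart, because the larger fall was in macrophages for 20 of 20 members against T cells and 14 of 20 against neutrophils, but for 8 of 16, or 50%, against NK cells. Nor can a smaller share of the cluster built here and led by Mmp12, Arg1 and Hmox1 be told apart from a change in its cells, since the median was -0.57 without them, between the bounds set for either answer. A difference in oxygen supply that goes with the genotype, tumour size and the place of sampling were not tested and stay open.

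The third pattern was that genes of gamma-delta type T cells (Cd163l1, Blk, Tcrg-C1, Ltb4r1 and others) were lower in KO T cells. Free RNA of other cells, which reaches the droplets of every type, is argued against as the whole cause for Cd163l1, Blk, Tcrg-C1 and Serpinb1a: WT T cells held at least 8.84 times the highest level among NK cells, macrophages, osteoclast-gene cells, neutrophils and dendritic cells. For Tmem176b, Ltb4r1 and 5430421N21Rik, each about as abundant in 1 of these types, free RNA and lower RNA of T cells cannot be told apart, because the richest 5% of WT T cells held 1.52 times the even share of their UMIs, between the bounds set for either answer. A smaller share of such cells could account for the pattern: after thinning to 800 UMIs, T cells with UMIs of at least 2 of 4 called genes made up 11.0% and 13% in WT and 1.53% and 0.952% in KO (unthinned 15.6%, 22.6%, 2.56% and 1.61%), and the higher KO share was 0.139 of the lower WT share, though these genes were picked because they fell. Because the genes that define the share are those that fell, a smaller share and lower expression per cell cannot be told apart.

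Il17a, a cytokine of this cell type, had -5.53 (edgeR adjusted p = 0.0894) and Trdc, the delta chain constant gene, -1.34 (0.288) in T cells, and neither was called; both were chosen after their values were seen. Ltb4r1 stood at 100 CPM in WT neutrophils and 111 in WT T cells, Tmem176b at 303 in WT dendritic cells and 309, and 5430421N21Rik at 116 in WT NK cells and 138. Serpinb1a, Tmem176b and 5430421N21Rik were chosen after their values were seen. Over all 7 genes the richest 5% held 1.81 and 1.53 times the even share in WT replicates 1 and 2, and over the 3 genes left open 1.65 and 1.38. B cells and mpDC were not compared for these genes. All 200 thinning draws gave a ratio of KO to WT share between 0.0817 and 0.245. Thinning left out 31 cells of WT replicate 1 and none elsewhere among T cells.

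For keratin-expressing CD45- cells, 3 further values were computed. Of the 519 called genes measured in keratin-expressing cells of the CD45+ libraries, 451 (86.9%) had the same sign there. Of the genes called higher, 17.1% were more abundant in KO macrophages than in KO keratin-expressing cells, against 33.8% of all genes tested. Without the Acta1 cluster 98.7% of the called genes were still called with the same sign. Loss of Ripk1 was not separated here from other differences between the injected WT and KO lines.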
